A study of Mus musculus with 6 samples.

How the data were processed

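RNA was measured in hearts of 11-month-old mice with a cardiomyocyte-specific deletion of Ybx1 (3 hearts) and of littermate controls (3 hearts), as separate libraries named by group and heart number. Per the labels' protocols, total RNA was taken up in TRIzol after homogenisation, cDNA was primed with anchored oligo(dT), and libraries were made by second-strand synthesis, tagmentation and PCR amplification. Per the submitters' processing notes, the genome build was mm39 and the tools were STAR 2.7.11, SAMtools 1.22.1, featureCounts, Subread 2.1.1 and edgeR 4.0.16, with no role given for each. The annotation release, the treatment of reads that map to several places and the strand setting were not given in the sources used here. The library protocol as described includes no step that marks the strand of a transcript, so reads of genes that overlap on opposite strands were treated as uncertain.

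The deposited table holds estimated counts and CPM for 78409 genes in each library. The authors' deposited counts were not all whole numbers: between 21.3% and 22.7% of the genes detected in a library had a fraction of a read, as when reads are shared out between genes or places. The authors' deposited CPM equalled the count divided by the sum of the same column times 1000000, with no difference above 0.001 in any gene, so it carried no scaling factor between libraries. All 92 rows of spike-in controls held 0 counts. The total counts were 12270796, 13469419 and 14524785 in control hearts 1, 2 and 3 and 13456753, 14651934 and 15141525 in knockout hearts 1, 2 and 3. At these depths a share of counts such as that of mitochondrial rRNA had a Wilson score 95% interval of at most ± 0.024 percentage points. Such intervals cover counting error only, since reads carried no molecular identifiers. No pair of libraries agreed within sampling noise, so all 6 were counted as separate samples.

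The main test was fixed before the data were examined for a table of CPM alone, as limma-trend on log2(CPM + 0.5). Because the table also holds counts, the main test became edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts rounded to whole numbers, and limma-trend as first written was kept as an alternative (limma 3.58.1). Genes with CPM of at least 1 in at least 3 of the 6 libraries were tested, which left 13717 genes, 11588 of them protein-coding. Counts were scaled by TMM factors, and the CPM values printed for genes are normalised by these factors. Fold changes are knockout relative to control, standard errors were derived from the quasi-likelihood F statistic, and 95% confidence intervals from the t distribution with its degrees of freedom. Adjusted p-values are Benjamini-Hochberg values, two-sided, with a threshold of 0.05, over all tested genes or, where stated, adjusted over the list alone. Adjustment over the list alone takes no account of the number of lists, of which there were 48. The prior degrees of freedom were 4.68 and the common biological coefficient of variation 0.253. The exact permutation test of 3 against 3 hearts cannot give a p below 0.1. The p-values of single genes measure the spread between these 6 hearts.

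The gene lists were also fixed before the data were examined, from general knowledge of heart biology, and none was chosen on these samples. The 29 function lists were the Y-box and cold-shock-domain family, YBX1 partner mRNP and stress-granule proteins, sarcomere and Z-disc, fetal gene program and hypertrophy, calcium handling, ion channels and conduction, fatty acid uptake and oxidation, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, tricarboxylic acid cycle and pyruvate metabolism, glycolysis and glucose uptake, cytosolic ribosomal proteins, translation factors, splicing factors, integrated stress and unfolded protein response, heat shock and chaperones, oxidative stress and NRF2 targets, p53 targets with senescence and apoptosis, cell cycle, extracellular matrix and fibrosis, interferon response, inflammation and NF-kB targets, complement and acute-phase, angiogenesis and hypoxia, circadian clock, immediate early genes, glucocorticoid and fasting response, autophagy and protein degradation, and insulin, IGF and mTOR signalling. The 19 cell type lists were ventricular and atrial cardiomyocyte, fibroblast, endothelial, endocardial, lymphatic endothelial, smooth muscle and pericyte, macrophage and monocyte, dendritic cell, T and NK cell, B and plasma cell, neutrophil, erythroid, adipocyte, epicardial and mesothelial, Schwann and neuronal, lung epithelial, thymus and skeletal muscle of the chest, and X-inactivation and Y-linked. Lists share some members. The 41 lists with at least 5 tested genes entered camera with an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists, with camera using an estimated correlation and fry beside it. The preset value treats the genes of a list as nearly independent, so its p-values can miss spread between hearts that these genes share. Over the lists called, the estimated correlation ran from -0.104 (Y-box) to 0.884 (mitochondrially encoded mRNAs), with 0.235 for the immediate early genes.

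The genes named in the text followed a rule set at the same time. It took Ybx1 with its paralogues and pseudogenes, then genes past the threshold by size of change, then, where fewer than 10 passed, the 10 genes with the smallest p besides Ybx1. It also took the member of each list with the smallest p, the 2 most abundant members of 8 lists, and Nppa, Nppb, Myh6, Myh7, Col1a1 and Atp2a2. Some genes that this rule took are not reported here. Other genes named, such as further members of a list that was called, were chosen after their values were seen.

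The alternatives set beforehand covered other pseudocounts, no filter or a mean CPM of at least 5, other scalings, limma without the trend, robust empirical Bayes, library weights, DESeq2 1.42.0, the heart number as a block, the level of Y-linked genes as a covariate, removal of mitochondrial and haemoglobin genes, other thresholds, other set tests, and leaving out each library in turn. Planned values on whole reads recovered from the CPM steps were replaced by the deposited counts. Alternatives chosen after seeing the data were limma-trend as first written, library totals alone, a fit without the 2 libraries that express Xist, the share of TEC genes as a covariate, and protein-coding genes alone. The steps were tested on simulated data drawn from the means and library sizes of the 13717 genes, with 200 genes changed in each of 5 runs. In this comparison of 3 against 3 libraries 20.6% of the genes changed 2-fold and 87.2% of those changed 4-fold were called, and 0.037% of the unchanged genes. A list shifted by 0.5 on the log2 scale was called in 5 of 5 runs by camera with the preset correlation and in 0 of 5 with an estimated correlation. Of the 40 other lists per run, camera with the preset correlation called 3 in all over the 5 runs. The simulated genes were drawn independently and no library stood apart, so these rates may not hold for the real libraries. GENCODE M21, which is on another build than mm39, was used only for gene order, strand and transcript length, and no coordinates are given. The shares of exons of Ybx1 were not analysed here. Figures were drawn with matplotlib.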

Results

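The study compared hearts of 11-month-old mice in which Ybx1 had been deleted in cardiomyocytes with hearts of littermate controls. Ybx1 encodes a Y-box protein with a cold-shock domain that binds RNA and DNA. The question was which heart transcripts differ at this age when cardiomyocytes lack the gene. Polyadenylated RNA of 3 knockout and 3 control hearts was sequenced to a total of 12270796 to 15141525 counts per library, and 13717 genes were tested.

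Ybx1 (ENSMUSG00000028639) fell in the knockout hearts, by edgeR's quasi-likelihood test adjusted over the list alone. Its level was 854 ± 42.7 normalised CPM in control hearts and 162 ± 47.5 in knockout hearts (SD, n = 3 each), or 18.9% of the control mean. The 3 control hearts had 851, 813 and 898 CPM and the 3 knockout hearts 203, 172 and 110 CPM. The log2 fold change was -2.40 (SE 0.27, 95% confidence interval -3.01 to -1.79). The paralogue Ybx3 was at 79.0 ± 13.01 CPM in control and 72.9 ± 7.48 CPM in knockout hearts (log2 fold change -0.11, interval -0.56 to 0.33, and between -0.24 without control library 2 and 0.01 without control library 3). Ybx2 was at 9.64 ± 1.10 and 6.63 ± 1.501 CPM (-0.54, interval -1.04 to -0.04).

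For Ybx1 the Benjamini-Hochberg adjusted p of edgeR's test was 6.47e-05 adjusted over the list alone, which was kept in all 6 fits that left out a library, and 0.148 over all 13717 genes. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 hearts can give. Over all genes Ybx1 passed the threshold without knockout library 3 (edgeR adjusted p = 0.0154) and in DESeq2 (adjusted p = 2.05e-16). The pseudogene Ybx1-ps2, which can share reads with Ybx1 and is therefore uncertain, was at 3.12 ± 1.11 CPM in control and 0.362 ± 0.339 CPM in knockout hearts. All 6 measured members of the Y-box and cold-shock-domain list had a log2 fold change below 0 with TMM scaling, Ybx1 among them (Ybx3 was at 0.05 in limma-trend on the CPM), and camera called the list lower (adjusted p = 2.68e-04, and adjusted p = 0.488 with an estimated correlation). The 5 members other than Ybx1 gave an unadjusted camera p of 0.116.

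**Figure D1:**
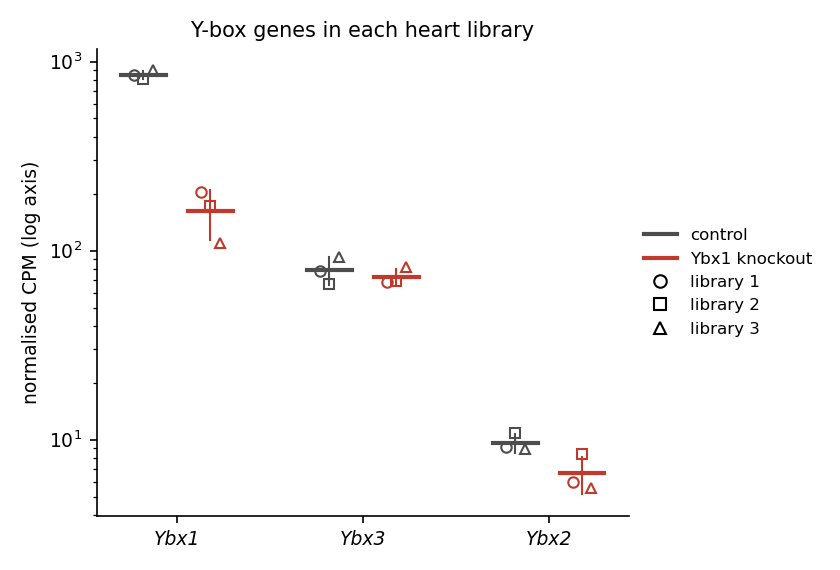
Normalised CPM (log axis) of Ybx1, Ybx3 and Ybx2 in the 3 control and 3 knockout heart libraries; points are libraries, horizontal bars group means and vertical bars ± 1 SD. For Ybx1 the knockout libraries lie between 110 and 203 CPM and the control libraries between 813 and 898 CPM.

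In the fetal gene program and hypertrophy list, edgeR adjusted over the list alone called Nppb, Ccn2 and Gdf15 higher in the knockout hearts. The list as a whole went both ways. Nppb, which encodes the natriuretic peptide BNP, rose from 184 ± 23.7 to 407 ± 115 CPM (SD, n = 3 each; log2 fold change 1.15, SE 0.26). Ccn2, the connective tissue growth factor, rose from 45.6 ± 10.3 to 113 ± 29.3 CPM (log2 fold change 1.30, SE 0.27). Gdf15, a secreted stress cytokine, rose from 0.921 ± 0.396 to 4.81 ± 2.39 CPM (log2 fold change 2.35, SE 0.50). All 3 passed edgeR's test adjusted over the list alone (each adjusted p = 0.0125) and did not pass over all genes (each adjusted p = 0.694).

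Nppb, Ccn2 and Gdf15 were the members past the threshold, adjusted over the list alone, among the 22 measured genes of the fetal gene program and hypertrophy list. Nppa, the atrial natriuretic peptide, was at 149 ± 29.9 CPM in control and at 91.8, 258 and 106 CPM in knockout hearts 1, 2 and 3 (log2 fold change 0.03, interval -0.85 to 0.91, and from -0.61 without knockout library 2 to 0.29 without knockout library 1). Myh7, the slow myosin heavy chain, was at 825 ± 72.4 and 579 ± 63.4 CPM (-0.51, interval -0.97 to -0.05). Ankrd1, a stress-responsive ankyrin repeat protein, was at 993 ± 123 and 1656 ± 624 CPM (0.74, interval 0.04 to 1.44, and 0.44 without knockout library 2). Skeletal actin, Acta1, was at 275 ± 141 CPM in control hearts and at 40.2, 147 and 23.4 CPM in knockout hearts 1, 2 and 3. Camera called the list higher (adjusted p = 0.0230, and adjusted p = 0.601 with an estimated correlation), while 11 members lay above and 11 below 0 and their median was -0.004, near 0 and of a sign that turned in 5 of the 6 fits without a library (-0.009 to 0.316). The list's call was absent without control library 1 (camera adjusted p = 0.137) or knockout library 2 (0.398). Adjusted over the list alone, Nppb, Ccn2 and Gdf15 lost their calls without control library 1, control library 2 or knockout library 2 (edgeR adjusted p 0.0513 to 0.0758).

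The contractile and calcium-handling genes gave no call by edgeR or camera with all 6 libraries. Among the 33 measured sarcomere and Z-disc genes, 15 had a fold change above and 18 below 0 (camera adjusted p = 0.195). The list was called lower without control library 2 (camera adjusted p = 0.00863) or knockout library 2 (0.0245). Myh6, the adult myosin heavy chain, was at 5490 ± 527 CPM in control and 3531 ± 630 CPM in knockout hearts (log2 fold change -0.64, interval -1.20 to -0.08). Tcap, the titin cap protein, was at 1187 ± 128 and 722 ± 144 CPM (-0.72, interval -1.23 to -0.20). Myl2 was at 5047 and 4372 CPM (-0.21, and -0.07 without knockout library 1) and Tpm1 at 5044 and 4107 CPM (-0.30, and -0.18 without control library 3). In the calcium-handling list (23 genes, camera adjusted p = 0.852), the calcium pump Atp2a2 was at 1710 ± 365 and 2346 ± 885 CPM (0.46, interval -0.26 to 1.17, 0.11 without knockout library 3 and 0.28 without control library 2), and Hrc at 518 and 376 CPM. The pump inhibitor Pln was at 1136 CPM in control and 994, 1415 and 3100 CPM in the 3 knockout hearts (0.69, and 0.08 without knockout library 3). Of 31 ion channel and conduction genes (camera adjusted p = 0.623), the gap junction gene Gja1 was at 109 CPM in control and 118, 146 and 275 CPM in the 3 knockout hearts (0.72, and 0.28 without knockout library 3). For each gene named here edgeR's adjusted p over all genes was 0.694 or more.

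Over all 13717 genes, no gene passed a Benjamini-Hochberg adjusted p of 0.05 in edgeR's quasi-likelihood test. At unadjusted p below 0.05 there were 705 genes, 369 higher and 336 lower in knockout, where chance alone gives 686. DESeq2 on the same counts called 15 genes (7 higher, 8 lower), limma-trend 0, limma-trend with library weights 18, and edgeR without a filter on low values 133 of 33251 genes (61 higher, 72 lower). The unfiltered fit also called Xist lower (log2 fold change -1.10, SE 0.26), though each group held a heart that expressed it. The main fit gave Xist an SE of 2.13, so the unfiltered fit missed much of the spread between hearts there. In the weighted fit control library 1 had a weight of 9.68 and every other library 0.275 to 1.35. Its control mean thus rested mostly on that library. For 8707 genes, 63.5% of those tested, the 95% interval lay within 2-fold either way. The 3 knockout values lay all above the control values in 858 genes and all below in 799, which is 12.1% of genes where chance gives 10%.

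The genes with the smallest p besides Ybx1 were not past the threshold of edgeR over all genes. Sord (ENSMUSG00000027227), sorbitol dehydrogenase of the polyol pathway, was at 74.2 ± 4.01 CPM in control and 28.2 ± 5.53 CPM in knockout hearts (SD, n = 3 each; log2 fold change -1.39, SE 0.20, edgeR adjusted p = 0.327). Clcn1, a chloride channel of muscle, was at 6.33 and 1.78 CPM, Inka2, an inhibitor of the kinase PAK4, at 8.37 and 3.90 CPM, and Srrm4, a splicing regulator of neurons, at 2.49 and 6.28 CPM. By the same rule 4 noncoding or unclassified loci were taken, 9430062P05Rik at 9.60 and 3.94 CPM, ENSMUSG00000121780 at 7.34 and 2.63 CPM, Gm49891 at 4.06 and 10.7 CPM and Gm33424 at 2.14 and 11.0 CPM. DESeq2 called each of these 8 genes (adjusted p 1.25e-06 to 0.0311), and also Nppb, Ccn2 and Gdf15. The 8 genes were picked by edgeR's p on the same counts, so their DESeq2 calls are no independent support. Gm12927 (ENSMUSG00000085203), a noncoding RNA, had 1, 0 and 0 counts in the control hearts and 24, 21 and 47 in the knockout hearts. The edgeR log2 fold change was 5.81 (interval 4.17 to 7.45, adjusted p = 0.177). The ratio of the pooled counts was 76.7, with an exact 95% counting interval of 13.4 to 3063 that leaves out the spread between hearts. In GENCODE M21 Gm12927 is the next gene downstream of Ybx1 on the same strand and overlaps Cldn19 on the other strand, which had 0 counts in all 6 libraries.

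**Figure D2:**
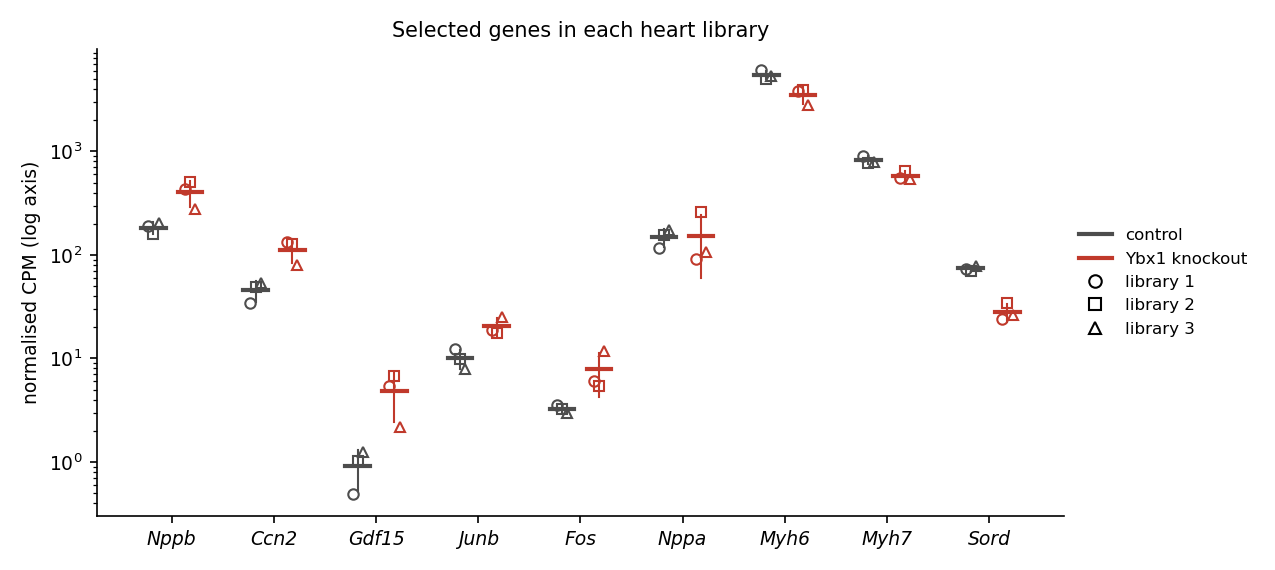
Normalised CPM (log axis) of 9 named genes in the 3 control and 3 knockout heart libraries; points are libraries, horizontal bars group means and vertical bars ± 1 SD. Nppb, Ccn2, Gdf15, Junb and Fos lie higher and Sord, Myh6 and Myh7 lower in all 3 knockout hearts, while Nppa overlaps between the groups.

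The immediate early genes, transcription factors and regulators induced within minutes of a stimulus, formed the list with the smallest camera p. Junb rose from 9.998 ± 2.16 to 20.4 ± 4.002 CPM (SD, n = 3 each; log2 fold change 1.03, SE 0.23) and Fos from 3.26 ± 0.288 to 7.82 ± 3.54 CPM (1.27, SE 0.32, and 0.83 without knockout library 3), in edgeR's test adjusted over the list alone (adjusted p = 0.0362 and 0.0400). Of the 21 measured members 19 had a fold change above 0, with a median of 0.69 (0.43 without knockout library 1), among them Dusp1 at 47.1 and 76.7 CPM, Nr4a1 at 7.16 and 14.5 CPM and Egr1 at 8.47 and 13.6 CPM, which did not pass. Camera called the list higher (adjusted p = 3.83e-08, and adjusted p = 0.601 with an estimated correlation). Junb and Fos lost their calls adjusted over the list alone without any of the 3 control libraries (edgeR adjusted p 0.0508 to 0.171). Over all genes neither passed (each edgeR adjusted p = 0.694), and adjustment over the list alone takes no account of the number of lists. Setting control 1, knockout 1 and knockout 3 against the other 3 hearts gave the list a smaller camera adjusted p, 7.60e-10, and 3 further splits called it (1.19e-07 to 0.00239).

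Among inflammatory genes, the calprotectin subunits of neutrophils rose, S100a8 from 1.26 ± 0.651 to 3.45 ± 1.26 CPM and S100a9 from 2.18 ± 0.701 to 4.96 ± 1.79 CPM (edgeR, each adjusted p = 0.0189 adjusted over the list alone, for 3 measured neutrophil genes). These calls were lost without control library 2, knockout library 1 or knockout library 2 (edgeR adjusted p 0.0537 to 0.0671), and the neutrophil list was too small for a set test. Neither gene passed adjusted over the 18 measured inflammation and NF-kB genes alone, or over all genes (each edgeR adjusted p = 0.694). Their calls in the neutrophil list take no account of the number of lists. The chemokine Ccl7 was at 1.27 and 2.43 CPM. Of 18 measured genes of inflammation and NF-kB targets, S100a8 and S100a9 among them, 14 lay above 0 (camera adjusted p = 6.87e-04, and adjusted p = 0.601 with an estimated correlation), and without knockout library 1 the call was lost (adjusted p = 0.209). Complement and acute-phase genes were called higher (13 of 14 above 0, camera adjusted p = 0.00254, and adjusted p = 0.601 with an estimated correlation), with the C1 inhibitor Serping1 at 36.4 and 61.7 CPM (log2 fold change 0.76, and 0.45 without knockout library 3). Setting control 1, control 2 and knockout 2 against the other 3 hearts gave the complement list a smaller camera adjusted p, 0.00194, and 2 further splits called it (0.0234 and 0.0263). The macrophage and monocyte list (camera adjusted p = 0.0947), with C1qa at 33.4 and 42.1 CPM, and the interferon response list (0.120), with Rigi at 6.38 and 4.42 CPM, were not called. The first was called higher without knockout library 3 (camera adjusted p = 0.0326) and the second lower without control library 3 (0.0158).

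Genes of antioxidant defence were called higher as a list. Of 26 measured oxidative stress and NRF2 targets 20 lay above 0, with a median log2 fold change of 0.39, which was 0.20 without knockout library 3 and 0.25 without control library 2 (camera adjusted p = 9.59e-05, and adjusted p = 0.601 with an estimated correlation). None passed edgeR adjusted over the list alone; the glutathione peroxidases Gpx1 and Gpx4 were at 38.6 and 56.4 CPM and at 219 and 330 CPM, and catalase, Cat, at 62.2 and 114 CPM. Autophagy and protein degradation genes were called higher (21 of 25 above 0, camera adjusted p = 0.00254, and adjusted p = 0.644 with an estimated correlation), with Gabarapl1, which encodes a protein of the autophagosome membrane, at 30.0 and 48.2 CPM. The metallothionein Mt2, the member with the smallest p of the glucocorticoid and fasting list (camera adjusted p = 0.273), was at 30.6 ± 11.0 and 66.6 ± 28.2 CPM, and this list was called higher without knockout library 3 (camera adjusted p = 0.00229). The autophagy call was lost with the share of TEC genes as a covariate (camera adjusted p = 0.135) and without the 2 libraries that express Xist (0.0511), the NRF2 call in neither. Of the 9 other splits of the 6 hearts 3 called the NRF2 list (camera adjusted p 0.00292 to 0.0121).

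Matrix genes were called as lists with no single member past edgeR's threshold. Of 37 extracellular matrix and fibrosis genes 24 lay above 0 (camera adjusted p = 0.0270, and adjusted p = 0.644 with an estimated correlation), and 13 of 14 fibroblast genes (camera adjusted p = 0.0319, and adjusted p = 0.601 with an estimated correlation). Collagen Col1a1 was at 28.8 ± 10.4 CPM in control and 33.7 ± 4.82 CPM in knockout hearts (log2 fold change 0.22, interval -0.42 to 0.86, -0.05 without control library 2, 0.46 without control library 3 and 0.12 without knockout library 3). Thbs1, thrombospondin 1, was at 11.2 ± 2.01 CPM in control and 27.9, 41.0 and 8.62 CPM in the 3 knockout hearts (1.21, and 0.69 without knockout library 2). Timp3 was at 322 and 265 CPM (-0.28, and from -0.57 without knockout library 1 to 0.004 without knockout library 3) and Col4a1 at 169 and 164 CPM (-0.05, and from -0.24 to 0.17 without the same libraries). The fibroblast transcription factor Tcf21 was at 3.68 CPM in control hearts and at 4.28, 2.96 and 12.6 CPM in knockout hearts 1, 2 and 3 (log2 fold change 0.86, and -0.02 without knockout library 3). The matrix call was lost without control library 2 (camera adjusted p = 0.187) or knockout library 1 (0.450). The fibroblast call was lost without control library 2 (camera adjusted p = 0.127), knockout library 1 (0.182) or knockout library 3 (0.0916).

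**Figure D3:**
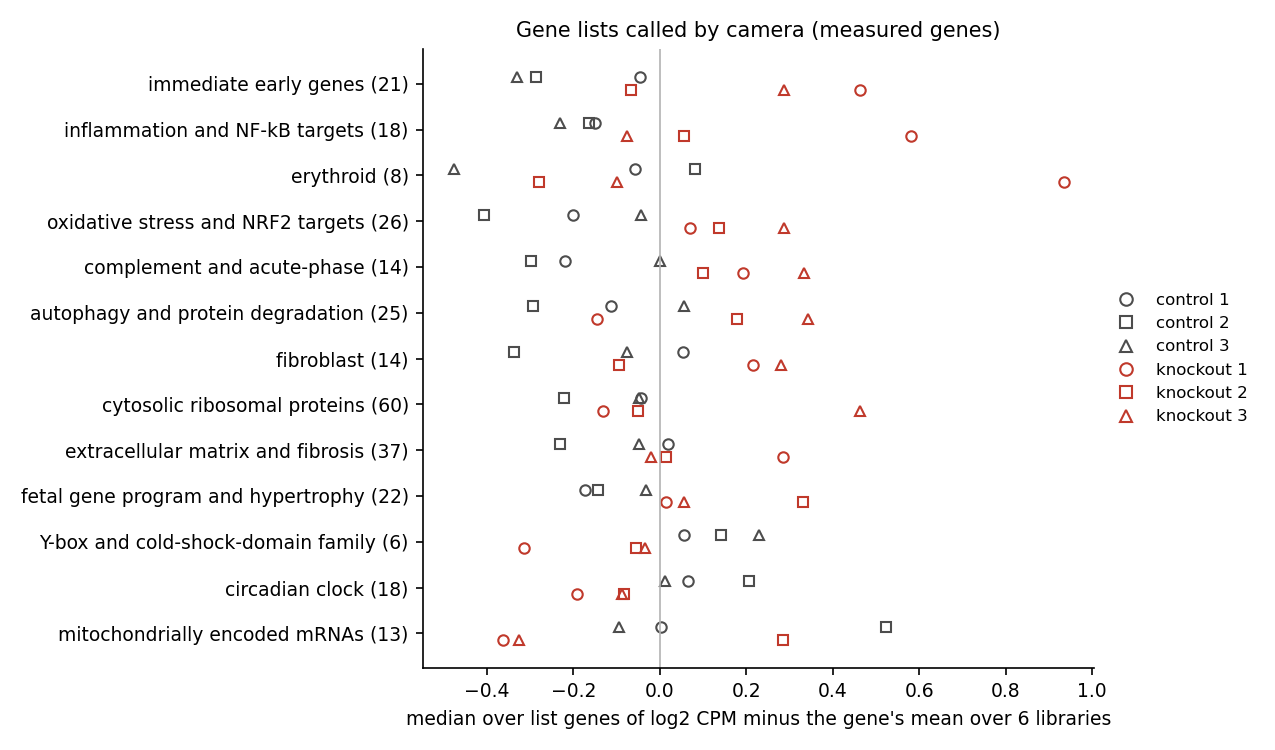
The 13 gene lists called by camera with the preset correlation, each with its number of measured genes; every point is the median over the list's genes of the log2 CPM of a library minus the gene's mean over the 6 libraries. In the immediate early list knockout library 1 stands at 0.463 and knockout library 2 at -0.068, below control library 1 at -0.046.

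The call of the ribosomal list rested on knockout library 3, which stood apart in its composition. This library had 10.7% of its counts in mitochondrial rRNA, where the other 5 had 20.5% to 26.3%, and 668 deposited CPM of the nuclear RNA Malat1, where the other 5 had 3317 to 7923 CPM. Genes of the class TEC, which the annotation uses for unspliced clusters of polyadenylated sequence, summed to 669 deposited CPM in it and to 1586 to 2497 CPM in the other 5. Cytosolic ribosomal protein genes were called higher (54 of 60 above 0, camera adjusted p = 9.40e-04, and adjusted p = 0.712 with an estimated correlation). Rpl34 was at 130 ± 12.4 CPM in control hearts and at 142, 139 and 327 CPM in knockout hearts 1, 2 and 3. Without knockout library 3 the ribosomal call was lost (camera adjusted p = 0.969).

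The 13 mitochondrially encoded mRNAs all lay below 0 (median log2 fold change -0.28, camera adjusted p = 0.00907, and adjusted p = 0.712 with an estimated correlation), with mt-Atp8 at 82.1 and 56.9 CPM (-0.53, and -0.29 without control library 2). The call was lost without control library 2 (camera adjusted p = 0.232, median -0.08) or knockout library 1 (0.209, median -0.18), but not without knockout library 3 (0.0338). Without knockout library 2 the median was -0.52. Without TMM factors, these mRNAs held 23.7%, 27.7% and 24.2% of counts in control hearts and 22.2%, 27.3% and 24.5% in knockout hearts. These shares overlapped between the groups, and the size of the fall depended in part on the TMM factors, which ran from 0.806 to 1.19. The nuclear-encoded genes of oxidative phosphorylation (39 of 49 above 0) and of fatty acid uptake and oxidation (31 of 39) were not called (camera adjusted p = 0.0624 each), and each was called higher in 7 and lower in 1 of 23 alternatives. Oxidative phosphorylation was called higher without control library 1 (camera adjusted p = 0.0290), control library 3 (0.00326) or knockout library 1 (1.10e-05). Fatty acid oxidation was called higher without control library 3 (camera adjusted p = 0.00815), knockout library 1 (0.00201) or knockout library 2 (0.0133). Fabp3, the heart fatty acid binding protein, was at 1235 ± 445 CPM in control and at 1103, 1815 and 4017 CPM in the 3 knockout hearts, and Mdh1, malate dehydrogenase, at 168 ± 60.9 and at 126, 228 and 724 CPM. Ucp2 was at 6.21 and 9.72 CPM, Lpl at 3568 and 4431 CPM (0.31, and 0.08 without knockout library 3), and Cox6a2 at 1126 and 1068 CPM (-0.08, and 0.18 without knockout library 1). Sdhd was at 47.4 CPM in control and 40.8, 65.5 and 159 CPM in the 3 knockout hearts (log2 fold change 0.90, and 0.16 without knockout library 3). Ndufa4 was at 1265 CPM in control and 634, 1349 and 2400 CPM in the 3 knockout hearts (0.21, and from -0.35 without knockout library 3 to 0.57 without knockout library 1). The tricarboxylic acid cycle list (camera adjusted p = 0.140) and the glycolysis list (0.965), with Pfkfb2 at 32.3 and 22.6 CPM (-0.51, and -0.26 without knockout library 3), were not called. The former was called higher without control library 3 (camera adjusted p = 0.00607) or knockout library 1 (8.34e-05). With the share of TEC genes as a covariate these 4 nuclear-encoded metabolic lists turned lower and were called (camera adjusted p 1.64e-06 to 0.0444). That covariate was lowest in knockout library 3, which also had the highest median of each of these 4 lists (0.224 to 0.688). The turns therefore cannot be told apart from the weight of that single library.

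**Figure D4:**
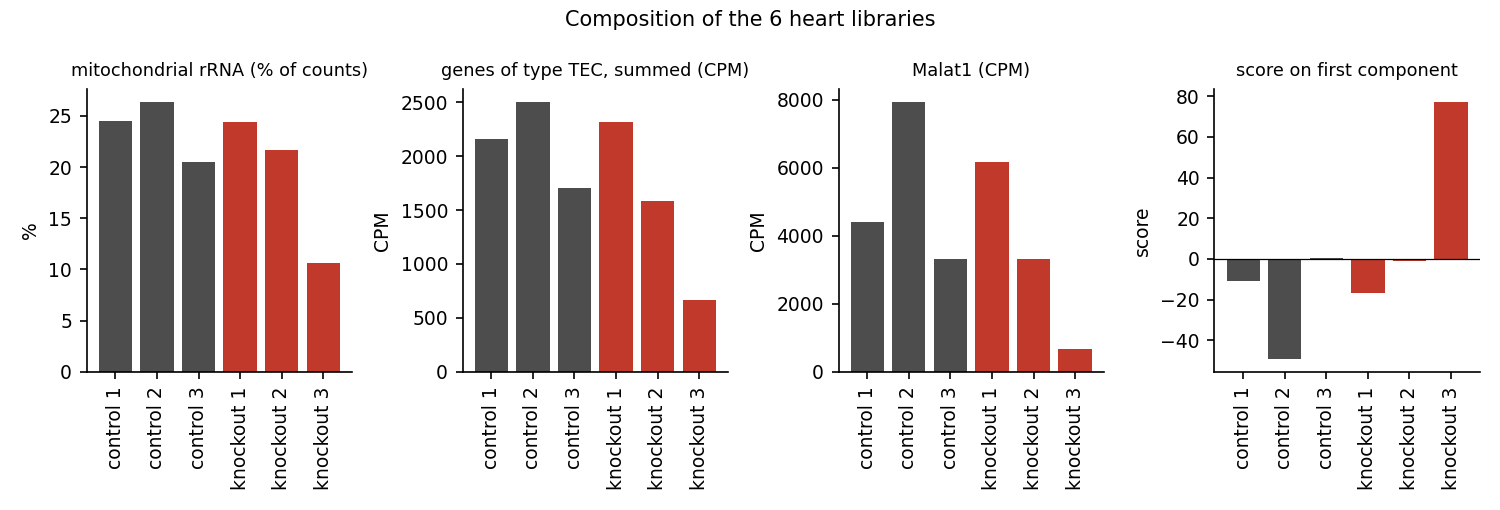
Composition of the 6 heart libraries, with bars for the percent of counts in mitochondrial rRNA, the summed CPM of TEC genes, the CPM of Malat1 and the score on the first principal component. Knockout library 3 is lowest in the first 3 panels and has a score of 77.2, where the other 5 lie between -49.2 and 0.7002.

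Genes of the circadian clock were called lower. Of 18 measured members 12 lay below 0 (camera adjusted p = 0.0188, and adjusted p = 0.601 with an estimated correlation), and none passed edgeR adjusted over the list alone. The period gene Per2 was at 30.9, 75.5 and 27.5 CPM in control hearts 1, 2 and 3 and at 25.8, 23.9 and 9.78 CPM in knockout hearts 1, 2 and 3. Per3 was at 18.7, 45.3 and 21.0 CPM in control hearts 1, 2 and 3 (28.3 ± 14.7) and at 13.1 ± 4.38 CPM in knockout hearts. The output transcription factors Hlf, Tef and Dbp were at 30.1 and 19.7, 106 and 61.0, and 44.0 and 30.4 CPM. Bmal1, which peaks in the opposite phase to them, was at 2.04 and 2.82 CPM. The call was lost without knockout library 1 (camera adjusted p = 0.193). The erythroid list was called higher (8 of 8 above 0, camera adjusted p = 0.0187, and adjusted p = 0.697 with an estimated correlation), with Bpgm at 17.4 and 26.9 CPM (0.63, and 0.22 without knockout library 1) and the globin gene Hba-a1 at 1499 CPM in knockout library 1 and 568 to 847 CPM in the other 5, and was lost without knockout library 1 (camera adjusted p = 0.861) or control library 3 (0.142).

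The remaining function lists were not called by camera with all 6 libraries. The YBX1 partner proteins of mRNPs and stress granules had 19 of 29 members above 0 (adjusted p = 0.466), with Elavl1, an RNA-binding protein, at 41.5 and 56.8 CPM. Translation factors had an adjusted p of 0.186, with Eef2, the elongation factor 2, at 382 and 256 CPM, and splicing factors one of 0.219, with Mbnl1 at 204 and 257 CPM. The camera adjusted p was 0.316 for the integrated stress and unfolded protein response, with Ddit3 at 9.04 and 6.73 CPM, Hspa5 at 258 and 331 CPM (0.36, and -0.05 without knockout library 3) and Hsp90b1 at 247 and 262 CPM (0.09, and -0.11 without it), and 0.231 for heat shock and chaperones, with Dnajb4 at 42.8 and 55.4 CPM. It was 0.144 for p53 targets, 0.149 for cell cycle, with Mcm2 at 2.44 and 4.45 CPM, 0.973 for angiogenesis and hypoxia, with Bnip3 at 47.1 and 76.2 CPM, and 0.140 for insulin, IGF and mTOR signalling, with Igfbp4 at 36.0 and 59.8 CPM. Without knockout library 3 the log2 fold change went from 0.37 to 0.16 for Dnajb4, from 0.69 to 0.46 for Bnip3 and from 0.73 to 0.44 for Igfbp4. Without that library camera called higher the p53 (adjusted p = 0.0281), cell cycle (0.0490) and insulin lists (0.0402).

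Markers of the other cell types gave no call by camera either. The adjusted p was 0.399 for ventricular and 0.973 for atrial cardiomyocytes (Stard10 at 15.2 and 10.6 CPM), 0.388 for endothelial cells (Pecam1 at 51.2 and 39.6 CPM), 0.124 for endocardial cells (Cytl1 at 6.43 and 10.9 CPM) and 0.760 for lymphatic endothelium (Reln at 1.92 and 1.14 CPM). It was 0.0669 for smooth muscle and pericytes (Smtn at 147 and 89.0 CPM), 0.523 for adipocytes (Lipe at 17.9 and 13.8 CPM) and 0.316 for Schwann and neuronal cells. Ventricular genes were called lower without knockout library 3 (camera adjusted p = 0.0414), atrial genes lower without it (0.0309) and endothelial genes lower without knockout library 1 (0.00649). Endocardial genes were called higher without control library 1 (camera adjusted p = 0.0413) or knockout library 2 (0.0133). Smooth muscle genes were called lower without control library 2 (camera adjusted p = 0.0481), control library 3 (0.0329) or knockout library 1 (0.0111). Without knockout library 3 the log2 fold change went from 0.77 to 0.22 for Cytl1, from -0.77 to -0.45 for Reln, from -0.37 to -0.23 for Pecam1, from 0.54 to 0.10 for H2-Ab1 and from 1.00 to 0.48 for Igkc. For Stard10 it went from -0.53 to -0.19 without control library 3. Lists with fewer than 5 measured genes were dendritic cells with 3 (H2-Ab1 at 8.47 and 12.3 CPM), B and plasma cells with 3 (Igkc at 5.33 and 10.8 CPM), epicardial and mesothelial cells with 3 (Gpm6a at 0.332 to 1.38 CPM in control and 0.607 to 2.45 CPM in knockout hearts), thymus and skeletal muscle of the chest with 1 (Tnni2 at 0.370 to 1.29 CPM in control and 0.910 to 1.61 CPM in knockout hearts), and T and NK cells and lung epithelium with 0 each. The X-inactivation and Y-linked list had an adjusted p of 0.689. Xist was at 384 CPM in control library 1 and 169 CPM in knockout library 3 and at 0.228 to 2.58 CPM in the other 4, which expressed the Y-linked genes, so each group held 1 heart of that kind.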

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

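The 5 settings named in the methods as chosen after seeing the data are marked "added". Over 25 alternatives the log2 fold change of Ybx1 stayed between -2.60 and -2.18, with an adjusted p from 2.05e-16 to 0.836, and passed 0.05 in 10. It passed with pseudocount 1 (-2.28, 1 gene called in all), without a filter (-2.38, 133 genes), in limma without the trend (-2.28, 2 genes), with library weights (-2.31, 18 genes), in DESeq2 (-2.41, 15 genes), with the Y-linked level as covariate (-2.43, 5 genes), without the 2 Xist libraries (added; -2.19, 5 genes) and with the TEC share as covariate (added; -2.18, 10 genes). With each library left out in turn Ybx1 lay between -2.60 and -2.19 and the genes called between 0 and 3, the 3 without knockout library 3. Of the 27 gene counts 17 were 0. Apart from the fit without a filter, Ybx1 was called in all 9 settings that called any gene and Gm12927 in 8. The unfiltered fit tested 33251 genes and called Xist lower (-1.10, SE 0.26, edgeR adjusted p = 0.0105), where the main fit gave an SE of 2.13. Its standard errors can thus miss the spread between hearts, and the weighted fit leaned on control library 1, so their calls are weak evidence. Why the fits named above call more was not tested.

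The heart numbers are shared by both groups, but nothing states that they pair the hearts. Deviations from the group means correlated at r = -0.112, 0.452 and 0.564 for hearts 1, 2 and 3, and 3 of 6 libraries matched their own number best. With the number as a block, Ybx1 was at -2.44 (adjusted p = 0.00424), 5 genes were called and 14 lists.

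The 13 lists called became 0 with an estimated correlation, 1 (the Y-box list) by fry, 8 with quantile normalisation, 22 without a filter and 22 with the TEC share as covariate. The Y-box, immediate early, NRF2 and complement lists were called in all 23 alternatives of camera with the preset correlation. Of the other 9, in fits on all 6 libraries, the fetal list was lost in 7, fibroblast in 6, matrix in 4, ribosomal in 3, mitochondrial mRNA and erythroid in 2 each, and inflammation, circadian and autophagy in 1 each. Of the 28 lists not called, 18 were called in at least 1 of these 23 alternatives. With the TEC covariate 4 lists turned from higher to lower and were called, fatty acid oxidation (adjusted p = 0.0444), oxidative phosphorylation (1.64e-06), tricarboxylic acid cycle (1.12e-05) and glycolysis (0.0124). The atrial list (adjusted p = 0.973, and 0.815 without knockout library 2) turned lower without knockout library 3 (0.0309), without the 2 Xist libraries (3.60e-07) and with the TEC covariate (1.12e-05), and the X and Y list turned higher with library weights (0.00992). In the atrial list the median stood highest in knockout library 3 (0.902) and, among controls, lowest in control library 1 (-0.389). Leaving these libraries out thus lowers the list by itself. The cause of the other turns was not tested. Scaling by library totals alone moved the median of all genes from 0.011 to 0.168 (log2). Of the named genes 19 changed sign in some alternative while past the threshold in neither fit. Depth limited values near 1 CPM, where a library held about 12 to 15 counts.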

Other observations

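The tests of sex and of TEC genes for knockout library 3 were chosen only after the result was seen, as was the use of 2 planned settings and of the splits as tests of the immediate early genes. The atrial genes below were also picked after their values were seen. In Sln, Myl4 and Myl7, 3 of the 12 measured genes of the atrial list, hearts of the same group differed by far more than the group means did. Sln, the atrial regulator sarcolipin, was at 0.647, 8.13 and 38.7 CPM in control hearts 1, 2 and 3 and at 0.272, 8.34 and 44.6 CPM in knockout hearts 1, 2 and 3. The atrial myosin light chains behaved alike, with Myl4 at 4.45, 27.0 and 96.6 CPM in control and 1.56, 27.8 and 92.5 CPM in knockout hearts, and Myl7 at 2.91, 21.6 and 74.4 CPM in control and 0.612, 14.3 and 46.7 CPM in knockout hearts. For these 3 genes the hearts with the same number in both groups differed by at most 2.25 on the log2 scale, while the range within a group was 4.44 to 7.36. The other 9 members were not compared by number, and the hearts of a group also spread in Nppa, at 116, 156 and 175 CPM in control and 91.8, 258 and 106 CPM in knockout hearts.

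Knockout library 3 had a score of 77.2 on the first principal component, and the other 5 libraries lay between -49.2 and 0.7002. An effect of sex that both groups share is argued against, since control library 1, the other library with Xist, scored -11.1, inside the range of the 4 libraries with Y-linked reads. An effect of sex in knockout hearts alone cannot be told apart, because knockout library 3 was the only knockout library with Xist. A smaller share of nuclear or unspliced RNA stays open, because the median log2 difference of the 364 tested TEC genes from the mean of the other 5 libraries, -2.003, restates the low TEC share that raised the question. A loss of long transcripts stays open too, since across 11557 protein-coding genes, which are not independent replicates, Spearman's rho of that difference with transcript length was -0.308, just past the bound of -0.3, where the other 5 libraries had values from -0.174 to 0.293. Genotype alone is argued against by knockout libraries 1 and 2, which scored -16.7 and -0.939, and other biological differences of this heart were not tested.

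Gm12927 had 92 counts in the 3 knockout hearts and 1 in the 3 control hearts. Reads of Cldn19, which overlaps it on the other strand, are argued against, because the summed Cldn19 counts rose by 0 while those of Gm12927 rose by 91. Transcription running on past the recombined Ybx1 gene is a candidate explanation that cannot be told apart from others here. The next tested gene downstream on the same strand, AU022252, had a log2 fold change of -0.130 (interval -0.58 to 0.32), and the same-strand genes upstream of Ybx1, Ppih and Ppcs, had 0.12 and 0.24 with intervals that hold 0, so the rise was seen in neither direction beyond Gm12927. Counts per exon or position, which could decide it, were not used here.

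The immediate early genes were called higher in the knockout hearts with the preset correlation (camera adjusted p = 3.83e-08), and not with an estimated correlation (adjusted p = 0.601). The low level of TEC and Malat1 reads in knockout library 3 is argued against as the whole of the rise. The list's median log2 fold change was 0.49 without that library and 0.69 with it. The camera adjusted p without it was 1.02e-13, but with the preset correlation other splits called the list too, so this p alone decides nothing. Differences between single hearts that the list's genes share cannot be told apart from an effect of the genotype, because the adjusted p of 0.601 decides nothing where the estimated correlation called a simulated shifted list in 0 of 5 runs. The list median of knockout library 2 (-0.068) lay below that of control library 1 (-0.046). Setting control 1, knockout 1 and knockout 3 against the rest gave this list an adjusted p of 7.60e-10, below the 3.83e-08 of the real grouping, and 3 of the other splits also called it.

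The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes past adjusted p 0.05 the real split gave 0 and the highest other split 0; against a count of 0 all 10 splits give as many by construction, so this comparison says nothing. For genes at unadjusted p below 0.05 the real split gave 705 and the highest other 2566, with 3 of the 10 splits at 705 or more. For lists called by camera with the preset correlation the real split gave 13 and the highest other 19, with 5 of the 10 at 13 or more and the lowest at 7. The split with 2566 genes and 19 lists set control 1, control 2 and knockout 1, the 3 libraries with the most TEC reads, against the other 3, which points to a structure of the samples that crosses the genotype.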
